A study of Homo sapiens with 4 samples.

How the data were processed

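RNA was measured by bulk sequencing of 4 libraries labelled LNCaP, 2 WT and 2 miR-3622-KO. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit. The deposited table gave FPKM (fragments scaled to transcript length in kilobases and to library size) for each gene and library, as computed by the authors. HISAT, StringTie, Cufflinks and GATK are named in the submitters' processing notes, with no role or version. The genome build, the gene annotation, the strand setting and the sequencing depth are not given in the sources used here. The table held no per-sample columns other than FPKM, so counts per gene were not available in it and no count model was fitted.

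The table had 21082 rows. Of these, 1721 held no value in any library and 1283 were listed at 0 in all 4. Rows for assembled genes without a name numbered 1768. Of the rows with an Entrez number, 19257 matched the RefSeq gene table of GRCh38.p14 and 57 did not. A spreadsheet had turned 29 gene symbols into dates or missing values, and these were restored from their Entrez numbers. Groups and replicate numbers were taken from the sample titles, not from the design note, which describes sorted cells. The low values stepped in multiples of a single fragment, worth 0.0456 to 0.0471 FPKM times kilobase, which implied 21200000 to 21900000 fragments per library. At that depth a gene of 1 kilobase at 1 FPKM rests on 21.2 to 21.9 fragments, so low genes are imprecise. The WT pair differed by more than counting noise (median dispersion 2.39 times that expected, over 2238 genes), as did the KO pair (19.35 times, over 2200 genes). All 4 were therefore kept as separate libraries.

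Genes at 1 FPKM or more in at least 2 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with trend=TRUE and robust=FALSE, KO minus WT, without a replicate block. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. On simulated data for 11965 genes, log2 changes of 1 and 2 were recovered for 100% of 100 changed genes each, and 0.238% of 11765 unchanged genes were called. Simulated noise was independent between genes and equal in both groups, unlike the spread of these libraries. The simulation therefore does not give the share of false calls here. Fixed gene lists, 34 in all, were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it. Replicate numbers were shared between the groups, and a fit with the number as a block was an alternative.

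Gene order came from the RefSeq table, used for names and neighbours. Windows of 40 tested genes were compared with 1000 random gene orders, and the interval with the largest standardized sum was taken as a segment. Transcript GC content, known for 96.4% of tested genes, and 3' UTR sequences came from the GENCODE annotation of GRCh38, which may differ from the build used by the authors. The GC correction removed a lowess trend (span 0.3) from each library. Seed sites of 7 bases were sought in the longest annotated 3' UTR, genes were matched on UTR length quintile, and the difference in medians was set beside all rearrangements of the same bases held by at least 30 genes. With values shuffled over 11516 genes and 0.1 added to those with TCAGGTG, the site came out at the 100th percentile of its rearrangements. Shuffling removes any link between base composition and fold change, so this does not measure sensitivity in the unshuffled values. No other site was simulated. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and statsmodels 0.14.6 was used for these steps, and matplotlib 3.10.9 for the figures.

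Genes were named by a rule fixed before the data were examined. It took every measurable gene of the reported-target and locus-neighbour lists; the 10 largest rises and 10 largest falls that passed, with a named symbol, separated groups and a mean of at least 5 FPKM in the higher group; up to 4 passing members of each list, or up to 2 of the most abundant where none passed; and the 5 most abundant genes that passed. It took 116 genes, of which 91 passed. Some of these genes are not reported here. The marker genes below the filter (KLK2, TMPRSS2, FOLH1, KRT19 and CDH1), VIM, FAS, the copies CBS and U2AF1, and the genes that bound the segments fall outside it and were chosen after their values were seen. Alternatives were robust estimation, quantile normalization, median centring, no filter, a filter at 5 FPKM, a pseudocount of 0.1, the replicate block, each library left out and, for the size of change, treat. The crossed pairing, the GC correction, the tests without the segment genes and, for the gene lists, robust estimation, both normalizations, both filters and the pseudocount were added after seeing the data.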

Results

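Bulk RNA-seq was carried out on 4 libraries of cells labelled as LNCaP, an androgen-sensitive line derived from a human prostate adenocarcinoma. Of these, 2 libraries came from wild-type cells (WT) and 2 from cells in which the miR-3622 genes were knocked out (miR-3622-KO). The miR-3622 family consists of small regulatory RNAs cut from a pair of hairpins that lie on opposite strands of the same site. The series' design note speaks instead of cells sorted by how active the miR-3622 family is, with no mention of a knockout. The groups here follow the genotype labels, so KO and WT mean what those labels say. The series title places the question in the p53-dependent gene network of prostate cancer. One table gave FPKM per gene, and the spacing of its lowest values implied 21800000 and 21200000 fragments for the WT libraries and 21800000 and 21900000 for the KO libraries. A total of 11965 genes reached 1 FPKM in at least 2 libraries and were tested. Across these genes the WT libraries correlated at 0.997 and the KO libraries at 0.989 (Pearson, log2 scale). Correlations between a WT and a KO library lay between 0.972 and 0.986. Genes are not independent replicates, so these values describe the libraries. The labels do not say that the 2 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

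The targeted locus was examined first. In the GRCh38 annotation MIR3622A lies on chromosome 8 from 27701677 to 27701759 on the plus strand. MIR3622B lies on the minus strand from 27701673 to 27701767. Both fall inside the single exon of AC013643.3, a transcript whose coding status is unproven, which spans 27701194 to 27703789. The table held 0 rows for a miR-3622 transcript, so the knockout could not be checked from these values. None of the 9 measured genes around the locus passed the test. ESCO2 had a log2 fold change of 0.18 ± 0.10 (SE) and CCDC25 of -0.01 ± 0.18. ZNF395 was at 7.19 ± 0.07 FPKM in WT and 4.54 ± 1.33 in KO (SD, n = 2 each), with an adjusted p of 0.0832 in limma.

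The libraries of both groups held little RNA of the genes that mark luminal prostate cells. The prostate protease genes KLK2 and TMPRSS2 were listed at 0 in all 4 libraries. The prostate membrane antigen gene FOLH1 did not exceed 0.17 FPKM, the luminal keratin gene KRT19 did not exceed 0.03, and the E-cadherin gene CDH1 did not exceed 0.22. Of 15 luminal genes on a fixed list, 4 reached 1 FPKM in some library, and KRT18 (13.4 ± 1.40 FPKM in WT, SD, n = 2) and HOXB13 (5.01 ± 0.13) had the highest WT means. Of 20 epithelial adhesion genes, 4 reached 1 FPKM. The intermediate filament gene VIM lay between 323 and 526 FPKM, the mesenchymal transcription factor gene SNAI2 between 52.3 and 66.8, and the neuronal hydrolase gene UCHL1 between 311 and 381. These were high members of mixed lists. Of 24 mesenchymal transition genes with a value, 12 reached 1 FPKM in some library and 5 reached 5 FPKM. The counts were the same for 24 neuroendocrine genes. None of the 3 tested luminal genes passed the test between the groups, although 2 of them fell when p was adjusted over the list alone. The epithelial junction gene CGN fell from 3.09 ± 0.08 to 1.64 ± 0.29 FPKM (adjusted p = 0.032, limma).

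**Figure D1:**
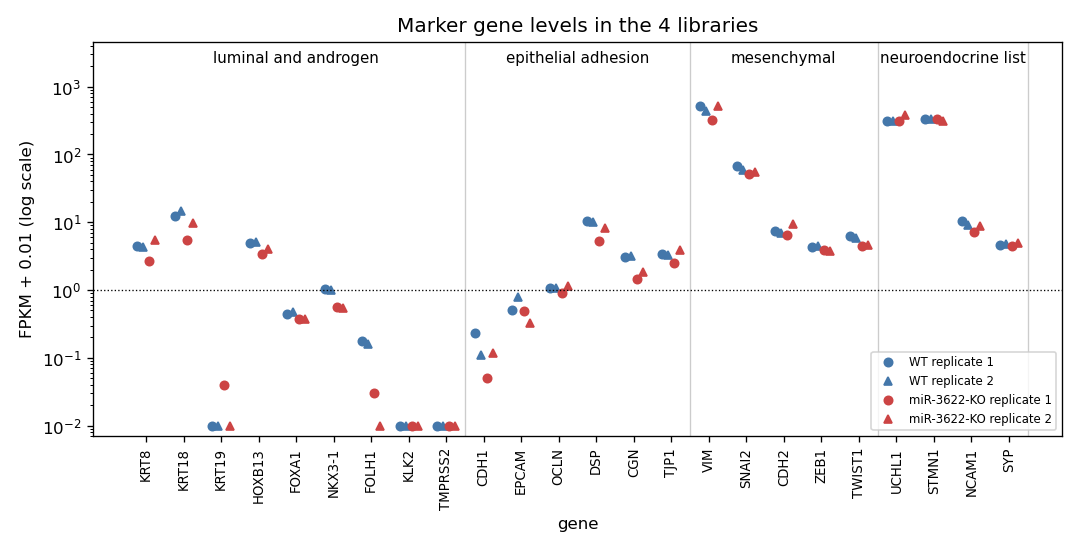
FPKM plus 0.01 on a log axis for marker genes in each of the 4 libraries, with WT in blue, KO in red, circles for replicate 1 and triangles for replicate 2; the dotted line marks 1 FPKM. CDH1 does not exceed 0.22 FPKM in the 4 libraries, and VIM lies between 323 and 526.

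In the main fit, more of the genes that passed were lower than higher in the KO libraries. In KO against WT, 1186 of 11965 genes passed an adjusted p of 0.05, with 313 higher and 873 lower. A change of at least 2-fold on the log2(FPKM + 1) scale was found for 131 of these, 35 higher and 96 lower. The cell cycle inhibitor gene CDKN1A was among the largest rises and the retinoic acid-producing enzyme gene ALDH1A2 among the largest falls. KO replicate 1 stood apart in base composition: its difference from the WT mean followed transcript GC content with a Spearman correlation of -0.51 across genes, against -0.11 for KO replicate 2. With this trend removed, an alternative added after seeing the data, 2608 genes passed and the split was 1151 higher to 1457 lower, or 44.1% higher against 26.4% before the correction. With quantile normalization the count was 1205 and the share higher was 38.0%. With no filter on low values, 5 genes were higher and 4 lower. Only 9 genes thus passed with no filter on low values. The count also fell when either WT library was left out and rose when either KO library was. The main fit pools the spread of both groups, which was unequal. Over genes, the SD of the log2 difference was 0.13 for the WT pair and 0.277 for the KO pair. With 1 KO library left, only the closer WT pair supplies the spread, so more genes pass.

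**Figure D2:**
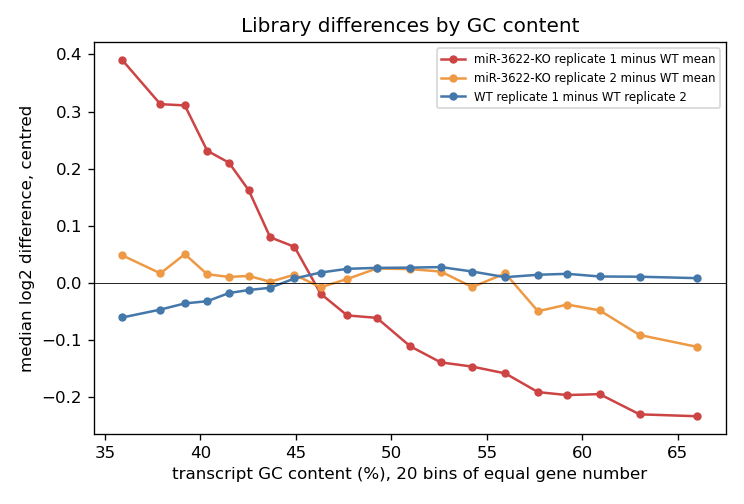
Median log2 difference, centred on all genes, in 20 bins of tested genes by transcript GC content (%), for each KO library against the WT mean and for WT replicate 1 against WT replicate 2. KO replicate 1 runs from 0.39 in the bin of lowest GC to -0.23 in the bin of highest GC, while KO replicate 2 runs from 0.05 to -0.11.

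Targets of the p53 pathway were higher in KO cells. Of 36 measured members of a list fixed before the data were examined, 13 rose, 1 fell and 22 did not pass. Adjusted over the list alone, 25 rose and 1 fell. The median log2 fold change was 0.46, and 32 of the 36 had a positive value. CDKN1A, which encodes the inhibitor p21, rose from 27.5 ± 0.62 to 77.8 ± 0.13 FPKM (SD, n = 2 each), a log2 fold change of 1.47 ± 0.09 (SE, limma adjusted p = 0.00623). MDM2, the ubiquitin ligase that acts on p53, rose from 22.4 ± 1.33 to 55.4 ± 9.92 FPKM (1.26 ± 0.14, adjusted p = 0.0144). TP53INP1, a p53-induced stress gene, rose from 1.61 ± 0.04 to 3.85 ± 0.11 FPKM. TP53I11 was the member that fell, from 11.1 ± 0.56 to 5.28 ± 0.54 FPKM. The list passed camera with a preset correlation (adjusted p = 2.55e-10) and fry (adjusted p = 0.0353), but not camera with an estimated correlation (adjusted p = 0.564 with an estimated correlation). Its median log2 fold change stayed positive without each library in turn, from 0.32 without KO replicate 1 to 0.52 without KO replicate 2.

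**Figure D3:**
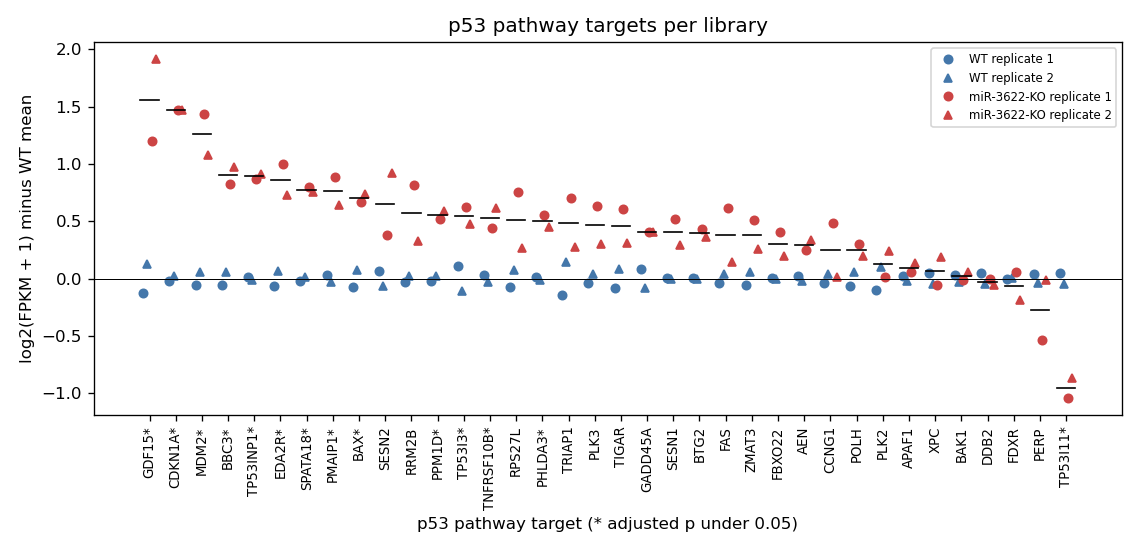
log2(FPKM + 1) of each of the 36 measured p53 pathway targets in each library, minus the WT mean, with WT in blue, KO in red and a black bar at the KO mean; asterisks mark genes with an adjusted p under 0.05. CDKN1A lies 1.47 above the WT mean, and 13 marked genes lie above it against 1 below.

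Of 27 measured apoptosis regulators, 4 rose and none fell, both over all genes tested and adjusted over the list alone. They were BBC3, PMAIP1, BAX and TNFRSF10B, which are also p53 targets. BAX, a pore-forming protein of the mitochondrial membrane, rose from 76.8 ± 5.93 to 125 ± 4.0 FPKM (SD, n = 2 each), and BBC3, an activator of BAX, from 12.3 ± 0.76 to 23.8 ± 1.77. PMAIP1 rose from 50.0 ± 1.48 to 85.7 ± 10.2 FPKM. The list missed the threshold in camera (adjusted p = 0.0727, and 0.803 with an estimated correlation) and passed in fry (adjusted p = 0.0227). Its camera call changed with the replicate block (0.026), without WT replicate 1 (0.0217) and without WT replicate 2 (0.0423). It also changed with the crossed pairing (0.0343) and the 5 FPKM filter (0.0324), both added for the lists after seeing the data. Among 7 measured genes of a list of reported miR-3622 targets and p53 axis members, CDKN1A and MDM2 rose and EGFR, the epidermal growth factor receptor gene, fell from 2.67 ± 0.43 to 1.41 ± 0.26 FPKM (adjusted p = 0.0448). Over the alternatives the adjusted p of EGFR ran from 0.00012 to 0.234, and the call was lost in 5 of them, among them the fit without WT replicate 1 (0.234) and quantile normalization (0.0552). MYC was at 87.0 ± 8.54 FPKM in WT and 52.9 ± 15.8 in KO (adjusted p = 0.0728), and ZEB1 and SNAI2 did not pass either. Adjusted over that list alone, 2 rose and 2 fell.

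Lists of growth signalling and lipid synthesis genes were lower in KO cells by camera at the preset correlation only, and none of these passed fry (adjusted p = 0.111 for Wnt targets and 0.131 for each of the others). Of 14 measured Wnt targets, 4 fell and none rose (8 and 0 adjusted over the list alone; median log2 fold change -0.35, camera adjusted p = 0.000941, and 0.803 with an estimated correlation). They included NKD2, an antagonist of Wnt signalling, from 5.91 ± 0.57 to 1.81 ± 0.23 FPKM (SD, n = 2 each), and the cyclin gene CCND1, from 11.5 ± 0.52 to 4.96 ± 2.14. Of 9 measured RAS-MAPK feedback genes, 4 fell and none rose (6 and 0 adjusted over the list alone; median -0.47, camera adjusted p = 0.00188, and 0.803 with an estimated correlation). The feedback inhibitor genes SPRED2, from 4.29 ± 0.40 to 1.69 ± 0.48 FPKM, and SPRY1, from 5.89 ± 0.29 to 3.27 ± 0.88, were among them. SPRED2 lies in the chromosome 2 segment described later. CCND1 is on both this list and the Wnt list, so these results share a falling gene. Of 17 measured fatty acid synthesis genes, 3 fell and none rose (7 and 0 adjusted over the list alone; median -0.39, camera adjusted p = 0.0033, and 0.803 with an estimated correlation). These were the lipogenic transcription factor genes SREBF1, from 8.37 ± 0.22 to 2.81 ± 1.51 FPKM, and MLXIPL, from 10.3 ± 0.31 to 4.25 ± 0.71, and the desaturase gene SCD, from 85.9 ± 4.27 to 47.6 ± 11.4. The camera call of the RAS-MAPK list was also lost with no filter on low values (adjusted p = 0.193), an alternative added for the lists after seeing the data.

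Of 12 measured mesenchymal transition genes, 3 fell and none rose (5 and 0 adjusted over the list alone; median log2 fold change -0.23, camera adjusted p = 0.0264, and 0.803 with an estimated correlation). These were the transcription factor gene TWIST2, from 3.94 ± 0.30 to 0.695 ± 0.39 FPKM (SD, n = 2 each), and the collagen genes COL5A1 and COL1A1, both below 3 FPKM in every library. The list's call was also lost in fry (adjusted p = 0.178) and without KO replicate 1 (0.0817). It was also lost with no filter on low values (0.0602) and with the 5 FPKM filter (0.235), while the lowest value over the alternatives was 0.00153. Of 27 measured genes of the amino acid stress response driven by ATF4, 3 rose and none fell (6 and 1 adjusted over the list alone; median 0.14, camera adjusted p = 0.0421, and 0.825 with an estimated correlation). They were the stress regulator NUPR1, from 6.05 ± 0.88 to 23.2 ± 8.20 FPKM, the glutathione-degrading enzyme gene CHAC1, from 10.5 ± 1.99 to 21.1 ± 5.46, and the transcription factor gene ATF5, from 5.60 ± 0.26 to 10.6 ± 1.55. That call was also lost in fry (adjusted p = 0.569), with quantile normalization (0.0917), with no filter on low values (0.0602) and with a pseudocount of 0.1 (0.0541). Without KO replicate 2 its direction turned, with a median of -0.09 and an adjusted p of 0.816, while without KO replicate 1 the adjusted p was 3.79e-08, the lowest over the alternatives. All 6 lists called by camera also passed after GC correction, with adjusted p from 8.08e-10 for the p53 targets to 0.0149 for the amino acid stress genes.

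The remaining lists did not pass camera in the main fit. Neither cytosolic ribosomal proteins (0 of 48 measured genes passed) nor oxidative phosphorylation (0 of 35) held a gene past the threshold, and the same was true of 19 androgen-responsive genes, 11 neuroendocrine genes and 5 basal epithelial genes. Adjusted over the list alone, 2 of the basal genes fell. The androgen-responsive list, with a median log2 fold change of -0.16, had a camera adjusted p of 0.0727, against 0.803 with an estimated correlation and 0.111 in fry. It passed camera after GC correction (0.0265), with no filter on low values (0.00728) and without KO replicate 1 (0.0428). The basal list (camera adjusted p = 0.101, and 0.803 with an estimated correlation) passed fry (0.0418) and passed camera after GC correction (0.0313). Of 5 measured androgen-repressed genes, 1 rose and 1 fell, over all genes tested and adjusted over the list alone. That list passed fry (adjusted p = 0.0227) but not camera (0.644, and 0.825 with an estimated correlation). Of 38 measured S phase genes, the cyclin gene CCNE2 rose and the nucleotide reductase gene RRM2, in the chromosome 2 segment, fell (0 and 1 adjusted over the list alone). Of 37 mitosis genes, 4 fell over all genes tested and adjusted over the list alone (PTTG1, KIF20A, BUB1 and CENPA), with CENPA, the centromeric histone gene in the chromosome 2 segment, going from 15.7 ± 0.74 to 7.82 ± 0.05 FPKM (SD, n = 2 each). The mitosis list (camera adjusted p = 0.445, and 0.825 with an estimated correlation) passed camera only without KO replicate 1 (0.0128). Among 15 measured short-lived stress transcripts that can mark handling, the chaperone gene HSPA8 rose from 457 ± 41.5 to 699 ± 15.4 FPKM, and JUN and IER3 fell (1 and 3 adjusted over the list alone). Markers of blood cells and of fibroblasts and endothelium were low: 4 of 20 and 3 of 20 reached 1 FPKM in some library. Among them ACTA2 rose, COL1A1 fell and the globin gene HBA1, which has a near-identical copy, went from 1.73 ± 0.25 to 0.68 FPKM; adjusted over each list alone, 1 gene rose and 1 fell in either list.

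Beyond the lists, the largest rises included SDSL, a serine dehydratase-like gene, from 5.04 ± 0.84 to 20.9 ± 3.56 FPKM (SD, n = 2 each; log2 fold change 1.85 ± 0.16, limma adjusted p = 0.0101). ACTA2, which encodes a smooth muscle actin, rose from 6.25 ± 0.13 to 21.2 ± 2.19 FPKM. ACTA2 overlaps the p53 target FAS on the opposite strand, and whether reads were counted by strand is not given in the sources used here, so its level is uncertain. The growth factor gene MDK rose from 41.5 ± 1.61 to 104 ± 33.9 FPKM, and the neuronal intermediate filament genes NEFM and INA rose from 10.9 ± 1.23 to 27.5 ± 2.23 and from 1.91 ± 0.28 to 5.60 ± 0.64. DOK3, from 4.44 ± 1.25 to 13.1 ± 0.93 FPKM, and ZDHHC11, from 4.21 ± 0.45 to 11.9 ± 2.23, completed the 10 largest rises. ANKRD1, a Hippo-YAP target, had a still larger log2 fold change of 2.16 ± 0.11 at a low level, from 0.28 ± 0.03 to 4.74 ± 0.47 FPKM. Of the 17 measured Hippo-YAP targets, 2 rose, 2 fell and 13 did not pass (2 and 10 adjusted over the list alone; median -0.36, camera adjusted p = 0.0833).

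Among the largest falls, ALDH1A2 went from 18.4 ± 0.35 to 3.38 ± 0.71 FPKM (SD, n = 2 each; log2 fold change -2.15 ± 0.14, limma adjusted p = 0.00623), and RARG, a retinoic acid receptor gene, from 7.0 ± 0.13 to 1.81 ± 0.53. The galactokinase gene GALK1 fell from 27.2 ± 1.81 to 8.48 ± 1.29 FPKM, the kinase gene MATK from 16.0 ± 0.21 to 4.75 ± 2.00, and the calcium channel gene CACNA1H from 5.46 ± 0.46 to 1.14 ± 0.21. COL18A1, PDE9A and PWP2 also fell, with log2 fold changes of -1.63, -1.72 and -1.62, and all lie in the chromosome 21 segment. CBSL had the most negative value (-4.34 ± 0.14, from 69.6 ± 6.01 to 2.50 ± 0.55 FPKM) and U2AF1L5 the next (-2.27 ± 0.46). Both are near-identical copies of other chromosome 21 genes, CBS and U2AF1, that can share reads with them, so these values are uncertain. The sum of CBS and CBSL was 171.2 FPKM in WT and 94.6 in KO, and that of U2AF1 and U2AF1L5 was 109.1 and 74.3. Both sums fell by less than the copies CBSL and U2AF1L5 alone. Of the 5 most abundant genes that passed, MTRNR2L2 and MTRNR2L8 rose and resemble mitochondrial ribosomal RNA, FTL rose, and RPS27A, in the chromosome 2 segment, and ACTG1 fell.

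Lower levels in KO cells were also arranged along the genome. Tested genes were placed in the order of the RefSeq annotation of GRCh38.p14, and the interval of each chromosome with the strongest common shift was located from the data. On chromosome 2, 291 neighbouring genes from ACP1 to GCFC2, beginning near the end of the short arm, had a median log2 difference of -0.44 after centring on all genes. It was -0.40 in KO replicate 1 and -0.49 in KO replicate 2, and 0.00 between the WT libraries. The other 485 tested genes of the chromosome had a median of 0.01. On chromosome 21, 48 genes from DSCR3 to DIP2A, at the far end of the long arm, had a median of -0.57, with -0.54 and -0.50 in the 2 KO libraries. Of the 339 genes in both segments, 158 passed the test, and 157 of these were lower, including the disulfide isomerase gene PDIA6 and the pyrimidine synthesis gene CAD on chromosome 2 and the phosphofructokinase gene PFKL on chromosome 21. They made up 13.3% of all calls, while the segments held 2.83% of tested genes. No other chromosome had a group of 40 neighbouring genes whose median exceeded 0.353 in size, the largest value in 1000 random gene orders.

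**Figure D4:**
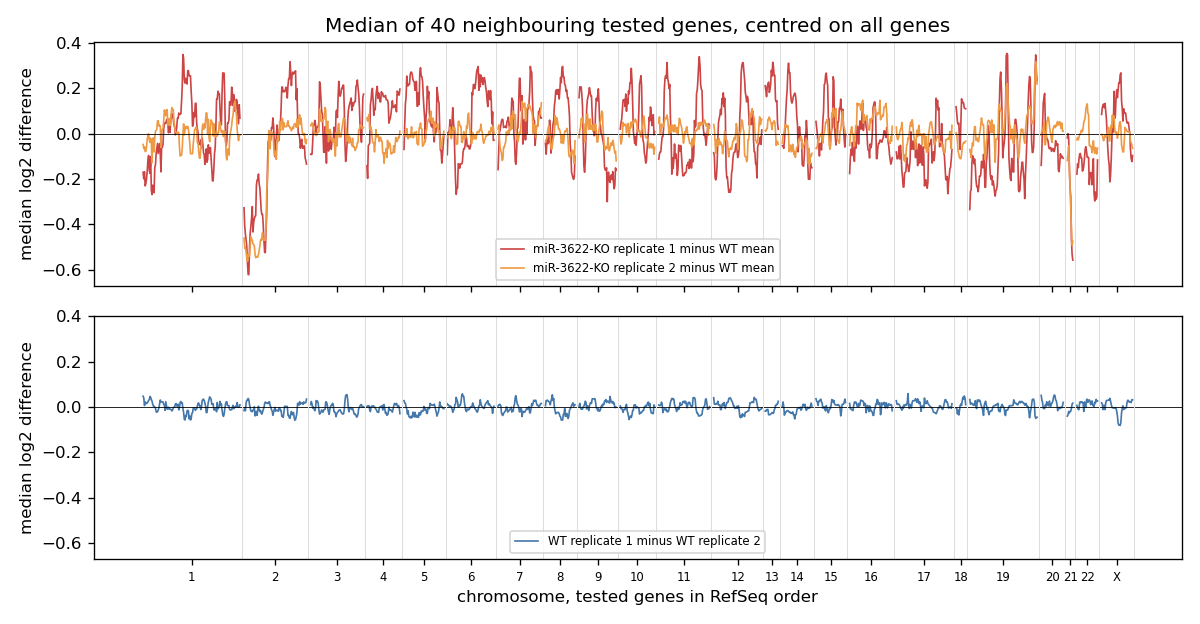
Median log2 difference of 40 neighbouring tested genes along each chromosome, in RefSeq gene order and centred on all genes, for each KO library against the WT mean (top) and for WT replicate 1 against WT replicate 2 (bottom). Both KO libraries drop over the first part of chromosome 2 and at the end of chromosome 21, where the segment medians are -0.44 and -0.57.

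Genes with a miR-3622 seed site in the 3' UTR were compared with genes without one, since removal of a microRNA lifts its repression of such genes. An annotated 3' UTR was found for 11516 tested genes (96.2%). The site TCAGGTG, matched by the shared seed of miR-3622a-3p and b-3p, was present in 2060 of them. Their median log2 fold change differed from that of genes without the site by -0.02 at matched UTR length (SD 0.03 between the KO libraries), which lay at the 58.5th percentile of 419 rearrangements of the same bases. The difference was -0.05 for the 849 genes with the miR-3622a-5p site CGTGCCT (SD 0.07, 88.5th percentile of 209) and -0.04 for the 2165 genes with the miR-3622b-5p site CCATGCC (SD 0.06, 91.4th percentile of 209). The differences depended on the KO library and on the GC correction. Without KO replicate 1 the values for the 3 sites were 0.00, 0.00 and -0.01, and without KO replicate 2 they were -0.04, -0.10 and -0.10. With the GC trend removed, an alternative added after seeing the data, all 3 differences were 0.00, at the 60.9th, 71.3rd and 72.2nd percentiles. In the main fit the rearranged words themselves had median differences of -0.02, -0.08 and -0.08 for the 3 sites. The negative values of the a-5p and b-5p sites thus lay above most of their rearrangements. For all 3 sites the value lay within the central 95% of the rearranged words, and no rise of site-bearing genes beyond that range was seen. MDM2 holds 2 copies of TCAGGTG and 5 of CCATGCC in its longest 3' UTR, which has 10837 bases. CDKN1A holds 0 copies of any of the 3 sites in 1539 bases.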

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

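The replicate block, the libraries left out, the filters, normalizations, pseudocount and set tests were planned; the GC correction, the crossed pairing and the tests without segment genes were chosen after seeing the data, as was every setting for the gene lists but the set tests, block and libraries left out. The count of 1186 changed genes became 9 with no filter on low values, 496 with the 5 FPKM filter, and 2608 with the GC correction. Without the segment genes, 835 passed (251 higher, 584 lower) and 116 changed at least 2-fold, although 1028 of the 1186 lay outside the segments. The cause of these moves was not tested. Leaving out 1 library gave 476 to 6233, the lone library of a group being assumed to vary like the other group. The 131 genes changed at least 2-fold became 9 with no filter, 79 with the 5 FPKM filter, 349 with a pseudocount of 0.1 and 2 with treat, which tests the fold itself, and 111 to 271 with 1 library left out. Replicate numbers did not pair the libraries (correlation of same-numbered deviations -0.27, with only 2 pairs), and the replicate block gave 1828 changed genes. Crossed pairing gave 3274 changed genes and 138 changed at least 2-fold. Camera called 6 lists, and 0 with an estimated correlation. Other alternatives gave 4 to 9, not always the same lists. In fry, 5 of the 6 were lost, leaving the p53 targets, and 3 other lists passed. The median of the amino acid stress list was 0.14, and ran from -0.087 without KO replicate 2, where it turned, to 0.386 without KO replicate 1. None of the 91 named genes that passed changed direction under any alternative, and 44 stayed past the threshold without each library in turn. Without the filter 3 of the 91 did. Both KO libraries lay on the same side of both WT libraries in all 91, so leaving out 1 library could not turn their direction. A comparison of FPKM with TPM was not run, because FPKM was the unit used here. Depth limits genes near 1 FPKM.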

Other observations

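Several lists that did not pass camera in the main fit still held genes that passed. Of 10 measured MHC class I presentation genes, 3 fell (HLA-E, HLA-F and TAP2) and none rose, and the list median was -0.51 (0 and 6 rose and fell adjusted over the list alone). The MHC list passed camera in 10 alternatives, the lowest adjusted p being 0.00642 with the replicate block, but not with an estimated correlation (0.803) or in fry (0.111). The transporter gene TAP2 fell from 16.1 ± 0.67 to 9.61 ± 0.91 FPKM (SD, n = 2 each; limma adjusted p = 0.0253), and reads of HLA genes can be shared between family members. Of 24 cholesterol synthesis genes, 5 fell, among them SQLE, DHCR7 and LSS, with LSS in the chromosome 21 segment (7 fell and 1 rose adjusted over the list alone). The epoxidase gene SQLE fell from 31.7 ± 0.77 to 20.4 ± 0.70 FPKM. The cholesterol list passed camera in 3 alternatives, without KO replicate 1 (0.00372), with quantile normalization (0.0477) and with no filter on low values (0.0381), but not with an estimated correlation (0.803) or in fry (0.111). Of 7 replication-dependent histone genes, HIST1H2BK, HIST2H2AA3 and HIST1H2AC rose (4 rose and 1 fell adjusted over the list alone), and histone genes can share reads with near-identical copies. The histone list passed camera in 4 alternatives, with the replicate block (0.026), the crossed pairing (0.0465), no filter on low values (0.0131) and without WT replicate 2 (0.00827), but not with an estimated correlation (0.803) or in fry (0.111). Of 18 genes of the NRF2 and metallothionein list, 3 rose, including NQO1, and 2 fell, including MT2A (7 and 5 adjusted over the list alone).

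All tests of explanations in this part were chosen only after the results they bear on were seen. The first pattern is the low level of most luminal and epithelial adhesion genes, and of some androgen-responsive genes, in libraries labelled with an androgen-sensitive line. Most androgen-responsive genes were not low: 20 of 26 with a value reached 1 FPKM and 15 reached 5 FPKM in some library. Of the genes on these lists, 30 stayed under 1 FPKM. Uncounted reads would leave them at 0 as a set, but 80% (24 of 30) had a value above 0 in some library. For the other 6, KLK2 and TMPRSS2 among them, which are listed at 0 in all libraries, uncounted reads cannot be told from absent RNA. Low androgen signalling alone in an epithelial cell would leave adhesion genes expressed, and only 4 of 20 reached 1 FPKM. Cells other than LNCaP under the label could give this pattern in both groups, with 4 of 15 luminal genes reaching 1 FPKM. A fixed list for other, androgen-independent prostate or common cell lines held 22 genes, 21 of them with a value. Of these, 10 reached 1 FPKM and 7 reached 5 FPKM in some library. No reference profile was analysed here, so other cells cannot be told apart from an LNCaP population that lost most luminal and epithelial adhesion expression.

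The second pattern is the lower level of neighbouring genes on chromosomes 2 and 21 in both KO libraries. A GC trend does not account for it, since the median of the 339 segment genes was -0.45 before and -0.48 after GC correction. By segment, the median went from -0.443 to -0.479 on chromosome 2 and from -0.569 to -0.465 on chromosome 21. Chance clustering is argued against, because the lowest median of 40 neighbouring genes was -0.58 and no random order exceeded 0.353 in size. Fewer copies of these segments in KO than in WT cells is a candidate explanation, and lower copy number would lower most genes of a segment in every KO library. Segments were therefore located from replicate 1 of KO minus WT alone and read in replicate 2, which shares no library with it. There 95.8% of their 335 genes lay below the genome-wide median, and 90.9% of 339 in the reverse order. Chromosomes 2 and 21 had been picked from all 4 libraries, and they ranked first and second of all chromosomes in either pair. Any cause shared by the KO libraries would give this agreement, so it does not favour fewer copies over other such causes. Before GC correction, the median levels over the full segments were 0.736 and 0.674 of WT. Whether KO cells lost or WT cells gained copies, or the segments were silenced in another way, was not tested, and calls inside them may follow dosage rather than miR-3622.

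The third pattern is the rise of p53 pathway targets. A GC trend does not account for it, since the list median was 0.46 before and 0.464 after correction. Lost repression through sites in their own 3' UTRs does not account for it as a whole, since 5 of the 13 targets that rose hold any of the 3 sites, and the 23 members without a site had a median of 0.46. An effect of miR-3622 through other genes may raise p53 activity, as may other differences between the WT and KO cell populations, of which the segments that hold 13.3% of the calls are an example. The knockout is confounded with such differences, so they cannot be told apart.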
